A study of Caenorhabditis elegans with 12 samples.

How the data were processed

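Polyadenylated RNA of whole worms was sequenced in 12 libraries, 3 in each of 4 groups. Reads were aligned with STAR 2.73a to the C. elegans assembly WBcel235 (ce11), and edgeR 3.24.3 was used, per the submitters' processing notes. The deposited table holds whole-number read counts per gene, made by the authors and not normalized. The sequencer was a BGISeq500, per the labels. The strand setting of the counting and the annotation release are not given in the sources used here. The table has 18761 genes and 3 summary lines that name no gene. Those lines, for multimapped, ambiguous and featureless reads, were kept out of library sizes and tests. As shares of gene counts and summary lines together, they came to 2.64 to 5.38%, 1.28 to 1.44% and 0.686 to 1.251%. Libraries held 41711402 to 44882654 gene counts. A floor of 3 counts corresponded to 0.0575 to 0.0855 CPM. Intervals and floors cover counting error only.

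Groups and replicate numbers came from the labels, and the feeding and collection of worms are per the labels' protocols. Nothing says whether the 3 libraries of a group came from separate cultures, so p-values measure the spread between these libraries, which may be technical. All 12 pairs of replicates differed by more than sampling noise (chi-square per degree of freedom 5.30 to 14.4), so each library was counted as 1 sample. The biological coefficient of variation was 6.18%. In a principal component analysis the first 3 components held 60.4%, 28.4% and 4.06% of the variance. Vitellogenin genes took 9.42% of gene counts in control, 0.363% with vha-6 RNAi, 0.621% in the libraries labelled elt-2 RNAi and 0.0883% in the combination. Mean TMM factors were 0.836, 1.00, 1.02 and 1.17 in that order.

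Genes were tested in R 4.3.3 with the quasi-likelihood test of edgeR 4.0.16 (robust, TMM scaling, low counts removed by filterByExpr), on 1 model of the 4 groups over the 12 libraries. This left 17479 genes and removed 1282. Comparisons were 5 contrasts between groups and 1 interaction. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Log2 fold changes are on the scale of normalized counts, with SE as the absolute value over the square root of F. CPM values use TMM library sizes. Values whose rounded form matches digits in a gene name listed in the scripts are printed with 1 or more further digits. Of the gene IDs 17691 matched the name table, and coordinates come from release 115 of the Ensembl annotation of WBcel235. Some deposited names have since changed: asp-10 is now hrg-7, F13D12.6 is ctsa-1.2, acox-5 is acox-1.5, F08A8.4 is acox-1.4 and F44G3.2 is argk-1.

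Gene lists, 34 in all, were fixed before the data were examined. They cover lysosomal, stress, immune and metabolic genes and markers of tissues and stages, and were tested with camera of limma 3.58.1 at a correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation. Whole worms were sampled, so list changes can reflect the share of a tissue. The rule for named genes was also fixed then. It took vha-6, elt-2, elt-7, hlh-30, cpr-5 and the paralogues vha-5, vha-7 and unc-32 in every comparison. It added the 7 called genes with the largest change in each direction among genes with an average log2 CPM of at least 2 and, for contrasts of groups, separated libraries. It further took up to 2 genes with the smallest adjusted p in each direction from lists called or with at least 25% of members called, of which some are printed.

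Folds against a group with no counts are lower bounds from the floor of 3 counts per library, and genes with 1 to 3 counts in a group are given as a ratio with an exact 95% counting interval. The alternatives were DESeq2 size factors, library size alone, no low-count filter, the test of DESeq2 1.42.0, a fit on only the groups compared, thinning to the smallest library, the replicate number as a block, a 2-fold minimum and leaving out each library. A 2-fold minimum with each other scaling, and gene lists with DESeq2 size factors, were added after the data were seen. All 12 libraries were used, and libraries were relabelled to see how many calls other splits give. The scripts were tested on simulated data. For vha-6 RNAi against control, over 17077 genes, 46%, 84%, 100% and 100% of genes changed by 1.25, 1.5, 2 and 4-fold were recovered, with 7 false calls. For the interaction, over 17071 genes, the shares were 16%, 58%, 86% and 100%, with 8 false calls. Of 31 simulated lists of 30 genes, the 1 shifted by 0.5 on the log2 scale was called and 0 of the others. To set the overlap of vha-6 effects beside chance, independent lists were assumed.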

Results

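Polyadenylated RNA was sequenced from whole Caenorhabditis elegans of the wild-type strain N2. RNA interference (RNAi) was delivered by feeding, in which worms eat bacteria that make double-stranded RNA against a gene. Worms ate the bacteria from the first larval stage and were collected after 2.5 days at 20 °C, as worms of the last larval stage or young adults. There were 12 libraries in 4 groups of 3. Control worms ate control RNAi bacteria alone. Another group ate 25% vha-6 RNAi bacteria with 75% control bacteria, and another 40% elt-2 RNAi bacteria with 60% control bacteria. The combination was 25% vha-6, 40% elt-2 and 35% control bacteria. The gene vha-6 encodes the intestinal a subunit of the V-ATPase, the proton pump that acidifies lysosomes, and elt-2 encodes the main GATA transcription factor of the intestine. The series concerns a transcriptional response to disturbed lysosomes. Of 18761 genes, 17479 were tested. Of the 118 genes named here, 23 have exons that overlap a gene on the other strand: C17H1.4, C17H1.5, C17H1.6, F08A8.4, F13D12.6, Y40H7A.10, Y48E1B.8, aagr-1, asm-3, asp-10, clec-266, clec-87, ctl-2, gba-1, hrg-3, nhr-97, rpn-9, sqt-3, unc-32, vha-5, vit-2, vit-3 and vit-4. For C17H1.4 and ech-9 a gene on the same strand overlaps. How strand was counted is not given in the sources used here, so the values of these genes are uncertain.

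Target genes were examined first. The locations in assembly WBcel235 are vha-6, WBGene00006915 on chromosome II, 11435210 to 11438452, minus strand, and elt-2, WBGene00001250 on chromosome X, 10481240 to 10483441, plus strand. Values below are mean CPM (counts scaled to library size) ± SD, n = 3 per group. The vha-6 transcript was at 334 ± 3.16 in control and 71.4 ± 5.56 in vha-6 RNAi libraries. It was at 56.5 ± 1.99 in the libraries labelled elt-2 RNAi and 12.28 ± 1.46 in the combination. The elt-2 transcript went against its label. It was at 11.2 ± 0.436 in control, 17.99 ± 3.42 in the libraries labelled elt-2 RNAi, 31.4 ± 1.07 with vha-6 RNAi and 50.8 ± 9.52 in the combination. A lower elt-2 transcript was therefore not measured in any group given elt-2 RNAi, and each direction below that involves those libraries takes their label as given. The transcript of cpr-5, a cathepsin B-like protease (WBGene00000785 on chromosome V, 1132598 to 1134036, minus strand), was at 393 ± 27.2, 1781 ± 44.7, 4.75 ± 0.296 and 12.62 ± 0.802 in control, vha-6, elt-2-labelled and combination libraries. In the same order hlh-30, the worm counterpart of the lysosomal regulator TFEB (WBGene00020930 on chromosome IV, 4014793 to 4034951, minus strand), was at 103 ± 4.33, 282 ± 15.5, 174 ± 9.61 and 267 ± 18.04.

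**Figure D1:**
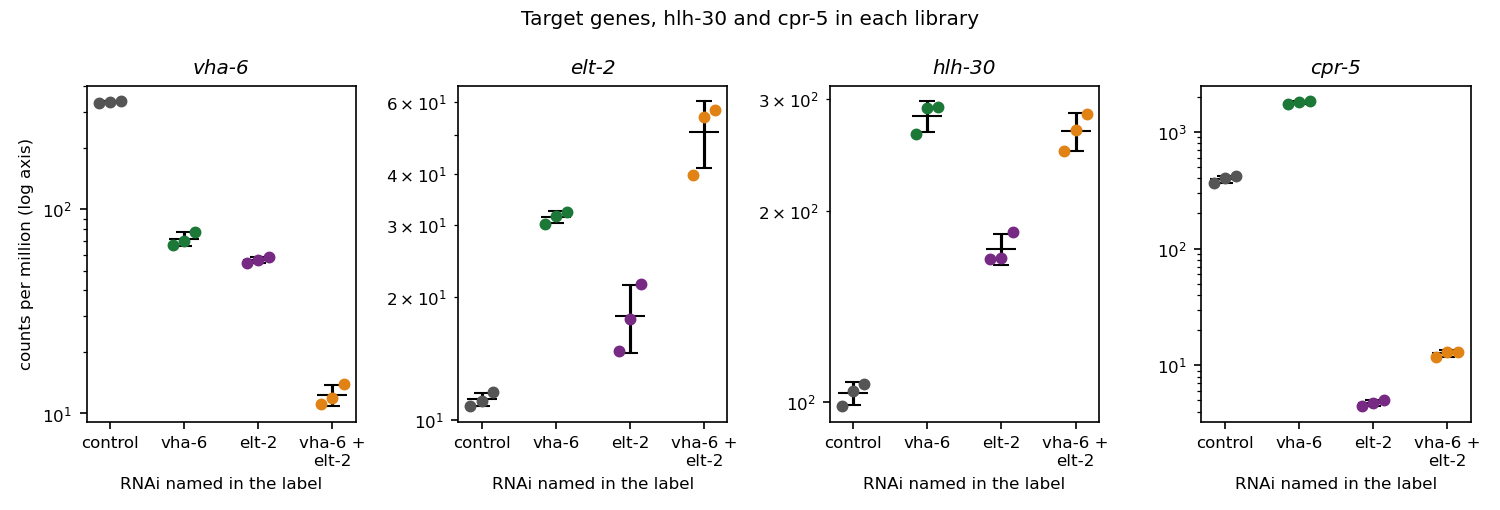
CPM on a log axis for vha-6, elt-2, hlh-30 and cpr-5, 1 point per library, with bars for mean ± SD (n = 3) in each of the 4 groups. The elt-2 points lie higher in the libraries labelled elt-2 RNAi than in control libraries, and cpr-5 is highest with vha-6 RNAi and lowest in the libraries labelled elt-2 RNAi.

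Lowering vha-6 asked which transcripts respond when the intestinal proton pump is reduced. Among transcripts that rose were 26 of 33 cathepsin-type proteases and 57 of 76 antimicrobial effectors. Among those that fell were 6 of 6 vitellogenins, which encode yolk proteins, and 36 of 36 germline and oocyte markers. Fold changes are given with log2 values ± SE, n = 3 against 3, and medians of lists are of log2 fold changes. The largest rises picked by the fixed rule were ugt-18 (603-fold, log2 9.24 ± 0.14), a UDP-glucuronosyltransferase, T22F3.11 (498-fold, log2 8.96 ± 0.18), ech-9 (483-fold, log2 8.92 ± 0.12), an enoyl-CoA hydratase homologue, clec-9 (451-fold, log2 8.82 ± 0.21) and clec-45 (329-fold, log2 8.36 ± 0.24), both C-type lectins, and hrg-2 (285-fold, log2 8.15 ± 0.14), a haem-responsive gene. The saposin-like gene spp-21 had no counts in control and rose at least 11.2-fold against the floor of 3 counts per library. The largest falls picked by that rule included the yolk protein genes vit-4 (1609-fold, log2 -10.65 ± 0.12), vit-3 (771-fold, log2 -9.59 ± 0.10), vit-5 (218-fold, log2 -7.77 ± 0.08) and vit-1 (176-fold, log2 -7.46 ± 0.08), with pud-3 (555-fold, log2 -9.12 ± 0.15), pud-4 (253-fold, log2 -7.98 ± 0.28) and sepa-1 (180.3-fold, log2 -7.49 ± 0.30), an autophagy receptor of embryos. Reads of vit-3, vit-4 and vit-5 can be shared between near-identical copies, so their single values are uncertain.

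Of the genes fixed in advance, vha-6 fell 4.68-fold (log2 -2.23 ± 0.06), while elt-2 rose 2.80-fold (log2 1.48 ± 0.15), elt-7, a second intestinal GATA factor, 1.93-fold (log2 0.95 ± 0.13), hlh-30 2.731-fold (log2 1.45 ± 0.06) and cpr-5 4.53-fold (log2 2.18 ± 0.06). The paralogue vha-7 fell 2.69-fold (log2 -1.43 ± 0.06). The paralogues vha-5 and unc-32 had log2 changes of 0.05 ± 0.06 and 0.08 ± 0.05 and were not called, but were -0.19 and -0.17 with DESeq2 size factors and 0.31 and 0.34 with library size alone, all 4 called. Of 22 measured V-ATPase subunits, 16 rose, 4 fell and 2 were not called (median 0.53, camera adjusted p = 0.096, but 0.039 with library size alone). The subunit vha-15 rose 1.91-fold (log2 0.93 ± 0.05). Of 33 measured cathepsin-type proteases, 26 rose and 7 fell (median 1.93, camera adjusted p = 6.2e-04, or 0.18 at estimated correlation). The aspartyl proteases asp-12 (134-fold, log2 7.06 ± 0.07) and asp-10 (16.6-fold, log2 4.05 ± 0.06) rose, whereas the cathepsin L gene cpl-1 (2.48-fold, log2 -1.31 ± 0.05) and asp-13 (5.88-fold, log2 -2.56 ± 0.08) fell. Of 32 measured lysosomal lipid, sugar and nucleic acid hydrolases, 25 rose, 4 fell and 3 were not called (median 0.92, camera adjusted p = 0.0097, or 0.13 at estimated correlation). Among these, the glucocerebrosidase homologue gba-1 (7.61-fold, log2 2.93 ± 0.06) and the acid ceramidase homologue asah-1 (6.26-fold, log2 2.65 ± 0.07) rose, and the acid sphingomyelinase homologue asm-3 (33.6-fold, log2 -5.07 ± 0.14) fell. Of 28 lysosomal membrane proteins and transporters, 17 rose, 8 fell and 3 were not called (median 0.60, camera adjusted p = 0.46). The haem transporter hrg-1 was higher by 10.3-fold (log2 3.36 ± 0.07). Among 28 autophagy genes, 10 rose, 16 fell and 2 were not called (median -0.38, camera adjusted p = 0.2). The p62 homologue sqst-1 rose 8.76-fold (log2 3.13 ± 0.06). For nutrient sensing at the lysosome, 4 rose, 15 fell and 2 were not called (median -0.54, camera adjusted p = 0.012, or 0.2 at estimated correlation).

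Effectors of defence and stress moved in both directions. Of 76 measured antimicrobial and immune effectors, 57 rose, 14 fell and 5 were not called (median 1.71, camera adjusted p = 8.4e-04, or 0.15 at estimated correlation). The saposin-like spp-2 (20.2-fold, log2 4.34 ± 0.08) and the lysozyme lys-4 (7.69-fold, log2 2.94 ± 0.06) rose, and the lectin clec-87 (16.03-fold, log2 -4.003 ± 0.07) fell. In the intracellular pathogen response, 29 rose, 1 fell and 13 were not called (median 1.59, 1.46 with genes at 0 at their bound, camera adjusted p = 0.0042, or 0.18 at estimated correlation). An example is the Skp1-related gene skr-3, higher by 4.72-fold (log2 2.24 ± 0.06). Endoplasmic reticulum unfolded protein response genes gave a split in which 20 rose and 6 fell (median 0.76, camera adjusted p = 0.0097, or 0.22 at estimated correlation). In the mitochondrial counterpart, 2 rose, 11 fell and 5 were not called (median -0.56, camera adjusted p = 0.019, but 0.064 with library size alone, or 0.18 at estimated correlation), with the chaperonin hsp-60 down 3.56-fold (log2 -1.83 ± 0.06). For DAF-16 targets, 16 rose, 6 fell and 3 were not called (median 0.74, camera adjusted p = 0.2). The noncoding RNA tts-1 rose 74.5-fold (log2 6.22 ± 0.08). Fatty acid oxidation genes showed that 15 rose, 25 fell and 4 were not called (median -0.28, camera adjusted p = 0.035, but 0.11 with library size alone, or 0.17 at estimated correlation). The acyl-CoA dehydrogenase acdh-1 fell 12.599-fold (log2 -3.66 ± 0.06). Of 221 measured nuclear hormone receptors, 175 rose, 17 fell and 29 were not called (median 1.17, camera adjusted p = 1.9e-06, or 0.0022 at estimated correlation). The receptor nhr-31 rose 4.08-fold (log2 2.03 ± 0.06).

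Markers of other tissues moved as well. Of 36 measured germline and oocyte markers, 36 fell (median -2.61, camera adjusted p = 7.1e-15, or 0.096 at estimated correlation). The oocyte maturation gene oma-2 (20.6-fold, log2 -4.37 ± 0.06) and the yolk receptor rme-2 (16.9-fold, log2 -4.08 ± 0.06) fell. Of 158 measured cuticle collagens, 28 fell, 11 were not called and the others rose (median 2.74, camera adjusted p = 5.8e-07, or 0.22 at estimated correlation). The collagens sqt-3 (14.6-fold, log2 3.87 ± 0.06) and dpy-13 (17.7-fold, log2 4.15 ± 0.06) rose and col-101 (22.1-fold, log2 -4.47 ± 0.06) fell. Of 25 measured molting and larval cuticle genes, 24 rose and 1 fell (median 3.31, camera adjusted p = 4.5e-07, or 0.13 at estimated correlation). One of them, mlt-8, rose 12.9-fold (log2 3.69 ± 0.06). Of 38 measured neuron markers, 34 rose, 3 fell and 1 was not called (median 1.19, camera adjusted p = 6.0e-05, or 0.018 at estimated correlation). The neuropeptide-processing protease egl-3 (3.46-fold, log2 1.79 ± 0.05) and the dense-core vesicle gene ida-1 (4.28-fold, log2 2.097 ± 0.07) rose. Of 14 measured pharynx markers, 14 rose (median 1.12, camera adjusted p = 0.0014, or 0.18 at estimated correlation). The gland gene phat-1 rose 22.6-fold (log2 4.50 ± 0.14). For intestine markers, 25 rose, 9 fell and 1 was not called (median 0.95, camera adjusted p = 0.019, or 0.18 at estimated correlation). Of 6 measured vitellogenins, 6 fell (median -7.61, camera adjusted p = 4.5e-05, or 0.18 at estimated correlation). Of 33 measured proteasome subunits, 33 fell (median -1.02, camera adjusted p = 1.5e-11, or 0.023 at estimated correlation). The subunit pas-4 fell 2.62-fold (log2 -1.39 ± 0.05). Of 31 measured epidermis and seam markers, 26 rose and 5 fell (median 3.45, camera adjusted p = 2.8e-05, or 0.17 at estimated correlation). Of 63 measured sperm markers, 22 rose, 26 fell and 15 were not called (median -0.06, but 0.20 with library size alone, mean 0.16 and test direction lower, camera adjusted p = 0.36). Of 28 measured body muscle markers, 17 rose, 5 fell and 6 were not called (median 0.23, but -0.02 with DESeq2 size factors, camera adjusted p = 0.44). The epidermis list shares 10 genes with the molting list and 9 with the collagens. For the remaining lists, the numbers higher and lower were 7 and 10 of 20 for cytosolic heat shock proteins, 25 and 23 of 61 for oxidative stress and glutathione genes, 17 and 7 of 26 for metal handling, 12 and 14 of 29 for fatty acid synthesis and desaturation, 49 and 10 of 73 for cytochrome P450s, 39 and 12 of 65 for UDP-glucuronosyltransferases, 113 and 25 of 176 for C-type lectins, 3 and 75 of 81 for cytosolic ribosomal proteins, 4 and 36 of 45 for mitochondrial respiratory chain and 12 and 6 of 18 for L4 and adult stage markers.

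Over all genes, edgeR called 8756 higher and 6186 lower, and 6209 and 3169 of these by at least 2-fold. Of the 34 lists, 22 were called by camera and 3 with an estimated correlation. Of the 50 genes picked for this comparison, 48 were called by edgeR, with a largest adjusted p of 3.8e-07, for elt-2. Adjusted over the list alone, member counts (higher, lower) differed, among the lists named here, for antimicrobial and immune effectors (58, 14) and C-type lectins (1 fewer, 25 as before). Scaling by DESeq2 size factors shifted the median log2 fold change of all genes by -0.25, and library size alone by 0.26, so small changes near 0 are relative to the TMM scaling.

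For the libraries labelled elt-2 RNAi, the comparison with control asked which transcripts depend on the intestinal GATA factor, and elt-2 counts were higher, not lower, in them: 1.60-fold (log2 0.68 ± 0.15). Lower in them were 22 of 33 cathepsin-type proteases, 6 of 6 vitellogenins and 29 of 44 genes of fatty acid oxidation. Higher were 34 of 43 genes of the intracellular pathogen response, a set induced by microsporidia and virus infection. Rises were the saposin-like spp-9 (981-fold, log2 9.94 ± 0.15), T22F3.11 (474-fold, log2 8.89 ± 0.18), F10A3.1 (421-fold, log2 8.72 ± 0.23), C53A5.11 (323-fold, log2 8.34 ± 0.27) and C17H1.6 (282-fold, log2 8.14 ± 0.25), the last now named pals-5, a marker of the intracellular pathogen response. The gene spp-21 rose at least 193-fold. C17H1.10, now pals-9, had 1 to 3 control counts (ratio 497, exact 95% interval 169.7 to 2410.1). The metallothionein mtl-2 had no counts in these libraries and fell at least 447-fold, and Y39B6A.21 fell at least 121-fold. Further falls were spp-4 (703-fold, log2 -9.46 ± 0.13), asp-13 (679-fold, log2 -9.41 ± 0.14), ech-7 (400.2-fold, log2 -8.64 ± 0.20), Y40H7A.10 (305-fold, log2 -8.26 ± 0.21) and clec-10 (288-fold, log2 -8.17 ± 0.27).

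In these libraries vha-6 fell 5.92-fold (log2 -2.57 ± 0.06) and cpr-5 fell 82.6-fold (log2 -6.37 ± 0.08). The gene elt-7 fell 2.19-fold (log2 -1.13 ± 0.14) and vha-5 1.14-fold (log2 -0.19 ± 0.06), whereas hlh-30 rose 1.69-fold (log2 0.75 ± 0.06). The log2 changes of vha-7 and unc-32 were -0.04 ± 0.05 and 0.11 ± 0.05, not called. With library size alone both were called, at 0.25 and 0.39, and vha-5 was 0.095, not called. With DESeq2 size factors vha-7 was -0.25, called, and unc-32 -0.10, not called. Of 33 measured cathepsin-type proteases, 8 rose, 22 fell and 3 were not called (median -1.37, -1.35 with genes at 0 at their bound, camera adjusted p = 9.7e-09, or 0.037 at estimated correlation). Here cpr-3 (39.2-fold, log2 5.29 ± 0.07) and asp-12 (9.89-fold, log2 3.31 ± 0.07) rose and the carboxypeptidase F13D12.6 (25.3-fold, log2 -4.66 ± 0.06) fell. Of 32 measured lysosomal lipid, sugar and nucleic acid hydrolases, 9 rose, 14 fell and 9 were not called (median -0.22, but 0.06 with library size alone, camera adjusted p = 1.1e-04, or 0.019 at estimated correlation). The lysosomal lipase lipl-5 (11.1-fold, log2 -3.48 ± 0.06) and the acid glucosidase homologue aagr-1 (21.1-fold, log2 -4.40 ± 0.08) fell. Among lysosomal membrane proteins, 11 rose, 7 fell and 10 were not called (median 0.03, but -0.18 with DESeq2 size factors, mean -0.34 and test direction lower, camera adjusted p = 0.22), with the scavenger receptor scav-1 down 32.5-fold (log2 -5.02 ± 0.11). Of 28 measured autophagy genes, 20 rose, 1 fell and 7 were not called (median 0.40, camera adjusted p = 8.1e-04, or 0.063 at estimated correlation). The autophagy genes sqst-1 (4.81-fold, log2 2.27 ± 0.06) and lgg-1 (2.41-fold, log2 1.27 ± 0.05) rose. Of 35 measured intestine markers, 12 rose, 19 fell and 4 were not called (median -0.44, camera adjusted p = 4.3e-04, or 0.054 at estimated correlation). Of 6 measured vitellogenins, 6 fell (median -5.94, camera adjusted p = 1.2e-09, or 0.037 at estimated correlation). The genes vit-5 (106-fold, log2 -6.73 ± 0.08) and vit-1 (74.1-fold, log2 -6.21 ± 0.08) fell.

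Of 43 measured genes of the intracellular pathogen response, 34 rose, 1 fell and 8 were not called (median 4.43, 4.40 with genes at 0 at their bound, camera adjusted p = 3.3e-11, or 0.019 at estimated correlation). The genes eol-1 (245-fold, log2 7.93 ± 0.12) and skr-3 (6.41-fold, log2 2.68 ± 0.06) rose. Of 76 measured antimicrobial and immune effectors, 28 rose, 36 fell and 12 were not called (median -0.24, but 0.04 with library size alone, camera adjusted p = 1.2e-04, or 0.049 at estimated correlation). The lysozyme lys-1 fell 14.3-fold (log2 -3.84 ± 0.06). For DAF-16 targets, 8 rose, 13 fell and 4 were not called (median -0.65, camera adjusted p = 0.0017, or 0.023 at estimated correlation). The RNA tts-1 (56.8-fold, log2 5.83 ± 0.08) rose and the lysozyme lys-7 (20.4-fold, log2 -4.35 ± 0.08) fell. Of oxidative stress genes, 9 rose, 28 fell and 24 were not called (median -0.27, camera adjusted p = 3.0e-06, or 0.023 at estimated correlation), among them the glutathione transferase gst-10, down 34.1-fold (log2 -5.09 ± 0.12). Among metal handling genes 9 rose, 14 fell and 3 were not called (median -0.77, camera adjusted p = 0.013, but 0.15 with DESeq2 size factors, or 0.049 at estimated correlation), and the cadmium-responsive cdr-4 rose 8.51-fold (log2 3.09 ± 0.06). In fatty acid synthesis, 4 rose, 19 fell and 6 were not called (median -0.58, camera adjusted p = 1.5e-07, or 0.054 at estimated correlation), and in oxidation, 8 rose, 29 fell and 7 were not called (median -0.39, camera adjusted p = 6.8e-09, or 0.0078 at estimated correlation). The elongase elo-6 (8.71-fold, log2 -3.12 ± 0.06) and acdh-1 (8.85-fold, log2 -3.15 ± 0.06) fell. For cytochrome P450s, 21 rose, 27 fell and 25 were not called (median 0.06, but -0.14 with DESeq2 size factors, mean -0.35 and test direction lower, camera adjusted p = 0.059, but 6.6e-04 with library size alone). The P450 cyp-35A2 fell 41.8-fold (log2 -5.38 ± 0.13).

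Markers of other tissues follow. Of 36 measured germline and oocyte markers, 5 rose, 13 fell and 18 were not called (median -0.07, but 0.21 with library size alone, camera adjusted p = 0.01, but 0.66 with library size alone, or 0.35 at estimated correlation). Of 63 measured sperm markers, 56 rose and 7 were not called (median 0.61, camera adjusted p = 2.0e-08, or 0.15 at estimated correlation). The sperm myosin spe-15 rose 1.90-fold (log2 0.93 ± 0.07). Of 28 measured body muscle markers, 1 rose, 20 fell and 7 were not called (median -0.32, camera adjusted p = 4.5e-08, or 0.011 at estimated correlation). The muscle gene dim-1 fell 1.93-fold (log2 -0.95 ± 0.05). Of 38 measured neuron markers, 32 rose, 1 fell and 5 were not called (median 0.52, camera adjusted p = 6.8e-05, or 0.014 at estimated correlation). The monoamine transporter cat-1 rose 8.29-fold (log2 3.05 ± 0.12). Of 81 measured cytosolic ribosomal protein genes, 1 rose, 79 fell and 1 was not called (median -0.46, camera adjusted p = 2.1e-25, or 0.13 at estimated correlation). One of them, rps-23, fell 1.56-fold (log2 -0.65 ± 0.06). Over all genes, edgeR called 6553 higher and 3254 lower, or 4731 and 5779 with DESeq2 size factors and 10711 and 1722 with library size alone, so the balance of directions depended on scaling. Of the 34 lists 27 were called, and 14 with an estimated correlation. Of the 46 genes picked for this comparison, 44 were called by edgeR, with a largest adjusted p of 0.0046, for vha-5. Adjusted over the list alone, member counts (higher, lower) differed, among the lists named here, for lysosomal lipid, sugar and nucleic acid hydrolases (9, 15), lysosomal membrane proteins and transporters (11, 8), autophagy (21, 1), intestine markers (13, 20), antimicrobial and immune effectors (29, 37), oxidative stress and glutathione genes (10, 30), fatty acid synthesis and desaturation (5, 19), cytochrome P450s (23, 27), sperm markers (57, 0) and body muscle markers (1, 21).

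**Figure D2:**
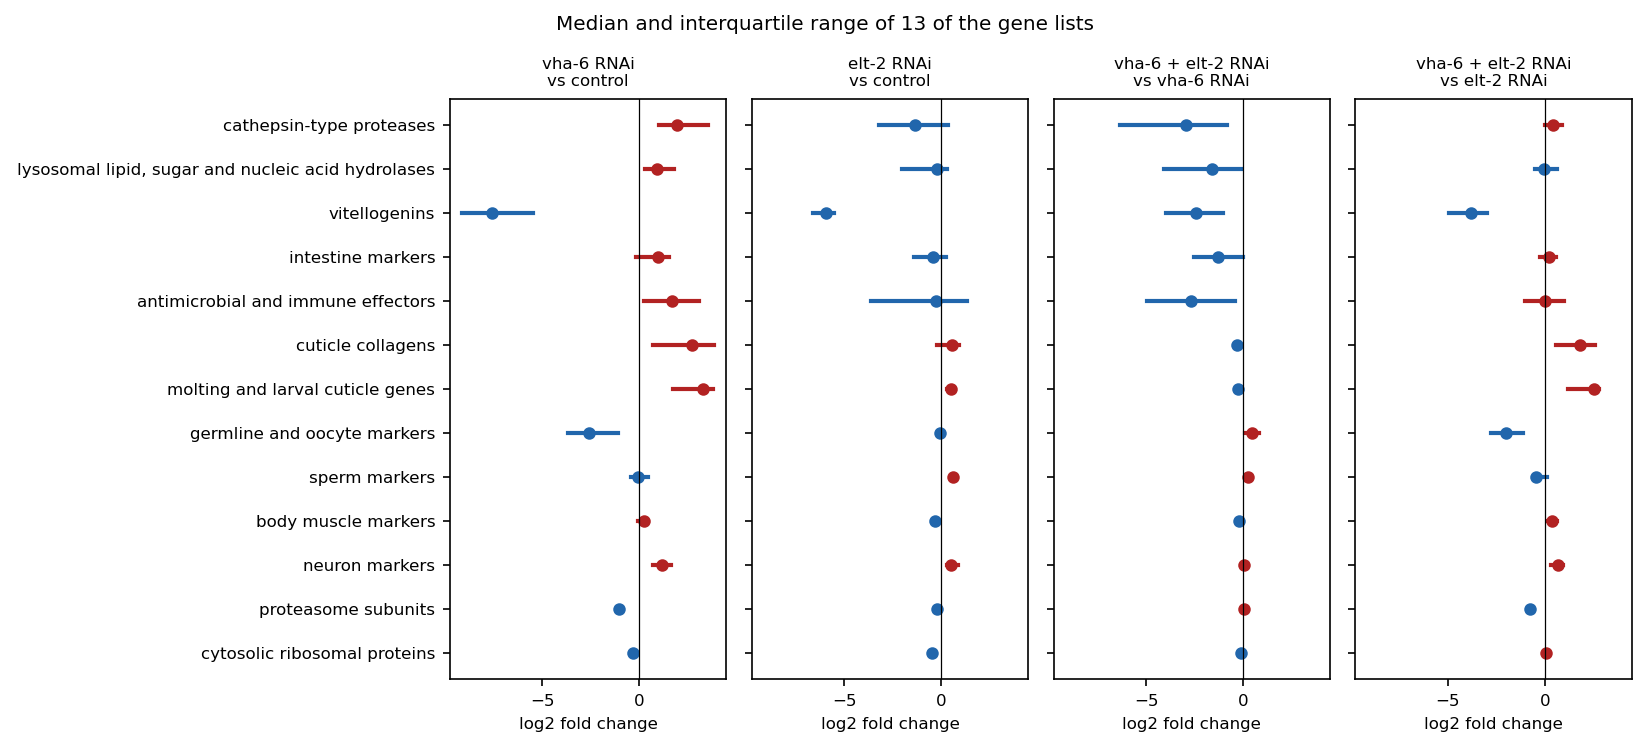
Median log2 fold change (points) and interquartile range (bars) of 13 gene lists in 4 comparisons, red above and blue below 0. Cathepsin-type proteases had medians of 1.93 with vha-6 RNAi and -1.37 in the libraries labelled elt-2 RNAi, and some medians near 0 change sign with the scaling.

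Adding elt-2 RNAi to vha-6 RNAi asked which of the transcripts present with vha-6 RNAi differ once elt-2 RNAi is fed too. Relative to vha-6 RNAi alone, 28 of 33 cathepsin-type proteases, 54 of 76 antimicrobial effectors and 19 of 25 DAF-16 targets were lower. Higher were 31 of 43 genes of the intracellular pathogen response. The pals genes C17H1.4 (116-fold, log2 6.86 ± 0.15), C17H1.5 (109-fold, log2 6.76 ± 0.12), C17H1.6 (142-fold, log2 7.15 ± 0.19) and T27E7.6 (221-fold, log2 7.79 ± 0.25) rose, as did F26F2.5 (166-fold, log2 7.38 ± 0.35) and T25B6.5 (96.8-fold, log2 6.60 ± 0.21). C17H1.13, now pals-11, had 1 to 3 counts with vha-6 RNAi alone (ratio 567, exact 95% interval 157 to 4686). The lectin clec-70 had no counts in the combination and fell at least 441-fold. ZC376.2, a carboxylesterase homologue, had 1 to 3 counts there (ratio 7.11e-04, exact 95% interval 8.60e-05 to 0.00257). Other falls were F48G7.5 (1399-fold, log2 -10.45 ± 0.18), spp-4 (1166-fold, log2 -10.19 ± 0.12), C17H12.6 (1005-fold, log2 -9.97 ± 0.22), Y39B6A.21 (848-fold, log2 -9.73 ± 0.18) and ech-9 (834-fold, log2 -9.70 ± 0.13).

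The target vha-6 was lower by 5.80-fold (log2 -2.54 ± 0.07) than with vha-6 RNAi alone, and elt-2 was higher by 1.62-fold (log2 0.69 ± 0.13), again against its label. Also, cpr-5 fell 141-fold (log2 -7.14 ± 0.07), elt-7 fell 3.44-fold (log2 -1.78 ± 0.13) and unc-32 rose 1.12-fold (log2 0.16 ± 0.05). The log2 changes of hlh-30, vha-5 and vha-7 were -0.08 ± 0.06, 0.07 ± 0.06 and 0.03 ± 0.06, not called, but 0.15, 0.30 and 0.26 with library size alone, all called, and vha-5 was 0.14, called, with DESeq2 size factors. Of 33 measured cathepsin-type proteases, 1 rose, 28 fell and 4 were not called (median -2.96, -2.82 with genes at 0 at their bound, camera adjusted p = 1.3e-24, or 0.0028 at estimated correlation). The one that rose was cpr-3 (2.11-fold, log2 1.07 ± 0.05), and F13D12.6 (52.05-fold, log2 -5.70 ± 0.06) fell. Of 32 measured lysosomal lipid, sugar and nucleic acid hydrolases, 19 fell and 13 were not called (median -1.59, camera adjusted p = 3.3e-12, or 0.0014 at estimated correlation). The genes gba-1 (51.7-fold, log2 -5.69 ± 0.07) and lipl-5 (30.8-fold, log2 -4.95 ± 0.06) fell. Among lysosomal membrane proteins, 7 rose, 12 fell and 9 were not called (median -0.14, but 0.09 with library size alone, camera adjusted p = 0.0099, or 0.12 at estimated correlation), with scav-1 down 50.9-fold (log2 -5.67 ± 0.11). Of 35 measured intestine markers, 5 rose, 23 fell and 7 were not called (median -1.31, camera adjusted p = 2.4e-09, or 0.0082 at estimated correlation). The protease asp-1 fell 7.80-fold (log2 -2.96 ± 0.07). Of 6 measured vitellogenins, 1 rose and 5 fell (median -2.44, camera adjusted p = 4.7e-05, or 0.1 at estimated correlation). The yolk gene vit-2 fell 51.9-fold (log2 -5.70 ± 0.10).

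Of 76 measured antimicrobial and immune effectors, 9 rose, 54 fell and 13 were not called (median -2.70, -2.64 with genes at 0 at their bound, camera adjusted p = 8.0e-18, or 0.0017 at estimated correlation). Here dod-23 (36.6-fold, log2 5.19 ± 0.07) and spp-9 (87.5-fold, log2 6.45 ± 0.14) rose and lys-4 (250.4-fold, log2 -7.97 ± 0.08) fell. Of 43 measured genes of the intracellular pathogen response, 31 rose, 4 fell and 8 were not called (median 2.87, camera adjusted p = 4.0e-15, or 0.007 at estimated correlation). The gene eol-1 rose 48.3-fold (log2 5.59 ± 0.08). For DAF-16 targets, 1 rose, 19 fell and 5 were not called (median -1.47, camera adjusted p = 4.3e-09, or 0.0016 at estimated correlation), with lys-7 down 27.3-fold (log2 -4.77 ± 0.08). Metal handling genes split so that 6 rose, 16 fell and 4 were not called (median -0.99, camera adjusted p = 9.3e-05, or 0.0082 at estimated correlation), and cdr-4 rose 5.09-fold (log2 2.35 ± 0.05). In oxidative stress, 2 rose, 34 fell and 25 were not called (median -0.34, camera adjusted p = 4.2e-07, or 0.016 at estimated correlation), with the catalase ctl-2 down 9.38-fold (log2 -3.23 ± 0.07). In fatty acid oxidation, 1 rose, 34 fell and 9 were not called (median -0.65, camera adjusted p = 7.1e-16, or 8.2e-04 at estimated correlation), with the acyl-CoA oxidase acox-5 down 6.94-fold (log2 -2.80 ± 0.06). Detoxification genes included cyp-35A2 (185-fold, log2 -7.53 ± 0.12) and ugt-18 (451-fold, log2 -8.82 ± 0.13), both lower. For cytochrome P450s, 19 rose, 32 fell and 22 were not called (median -0.34, camera adjusted p = 0.0057, or 0.079 at estimated correlation), and for UDP-glucuronosyltransferases, 11 rose, 35 fell and 19 were not called (median -0.65, camera adjusted p = 6.6e-06, or 0.016 at estimated correlation). Of 36 measured germline and oocyte markers, 24 rose and 12 were not called (median 0.45, camera adjusted p = 4.7e-11, or 0.054 at estimated correlation). The oocyte gene puf-5 rose 2.19-fold (log2 1.13 ± 0.06). Of 25 measured molting and larval cuticle genes, 16 fell and 9 were not called (median -0.28, camera adjusted p = 0.0022, but 0.073 with library size alone, or 0.18 at estimated correlation). The collagen dpy-7 fell 1.36-fold (log2 -0.44 ± 0.07). Over all genes, edgeR called 2930 higher and 3378 lower, or 4061 and 2827 with DESeq2 size factors and 7500 and 2036 with library size alone. Of the 34 lists 31 were called, and 15 with an estimated correlation. Of the 41 genes picked for this comparison, 38 were called by edgeR, with a largest adjusted p of 0.0087, for unc-32. Adjusted over the list alone, member counts (higher, lower) differed, among the lists named here, for cathepsin-type proteases (1, 29), lysosomal lipid, sugar and nucleic acid hydrolases (0, 20), intestine markers (5, 24), antimicrobial and immune effectors (10, 56), metal handling (7, 17), oxidative stress and glutathione genes (2, 37), cytochrome P450s (19, 33), UDP-glucuronosyltransferases (11, 37), germline and oocyte markers (26, 0) and molting and larval cuticle genes (1, 16).

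Adding vha-6 RNAi to elt-2 RNAi asked what lowering vha-6 further changes. The libraries labelled elt-2 RNAi already had 56.5 CPM of vha-6 (control 334). In the combination, against them, 36 of 36 germline markers and 6 of 6 vitellogenins were lower. Higher were 118 of 158 cuticle collagens and 31 of 38 neuron markers. Rises included C17F4.3 (15.99-fold, log2 3.999 ± 0.21), C17F4.12 (13.7-fold, log2 3.77 ± 0.13), F17B5.1 (13.1-fold, log2 3.71 ± 0.28), ZK154.1 (11.3-fold, log2 3.50 ± 0.12) and F35D2.1 (11.2-fold, log2 3.49 ± 0.13), and the arginine kinase homologue F44G3.2 (11.5-fold, log2 3.52 ± 0.10). Y39B6A.21 had no counts in the libraries labelled elt-2 RNAi and rose at least 1.17-fold. Falls were sepa-1 (201-fold, log2 -7.65 ± 0.28), vit-4 (114-fold, log2 -6.83 ± 0.16), clec-266 (74.9-fold, log2 -6.23 ± 0.16), vet-6 (55.3-fold, log2 -5.79 ± 0.25), skr-7 (52.7-fold, log2 -5.72 ± 0.19) and C35E7.5 (37.9-fold, log2 -5.24 ± 0.14). The lectin clec-70 had no counts in the combination and fell at least 2.50-fold. The target vha-6 fell 4.59-fold (log2 -2.199 ± 0.07), vha-7 fell 2.57-fold (log2 -1.36 ± 0.06), and elt-2 rose 2.82-fold (log2 1.497 ± 0.14), hlh-30 1.53-fold (log2 0.62 ± 0.06), cpr-5 2.65-fold (log2 1.41 ± 0.08), vha-5 1.245-fold (log2 0.32 ± 0.06) and unc-32 1.09-fold (log2 0.13 ± 0.05). The log2 change of elt-7 was 0.30 ± 0.15, not called, but 0.33 with DESeq2 size factors and 0.50 with library size alone, both called.

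Of 33 measured cathepsin-type proteases, 20 rose, 7 fell and 6 were not called (median 0.44, camera adjusted p = 0.012, or 0.32 at estimated correlation). Here asp-8 (3.82-fold, log2 1.93 ± 0.06) and asp-10 (2.64-fold, log2 1.399 ± 0.05) rose and asp-12 (1.78-fold, log2 -0.83 ± 0.06) fell. For lysosomal lipid, sugar and nucleic acid hydrolases, 11 rose, 10 fell and 11 were not called (median -0.03, but 0.13 with library size alone, mean 0.10 and test direction lower, camera adjusted p = 0.99). Among autophagy genes, 3 rose, 19 fell and 6 were not called (median -0.37, camera adjusted p = 0.0079, but 0.071 with library size alone, or 0.16 at estimated correlation), with sqst-1 up 1.75-fold (log2 0.81 ± 0.05). Of 6 measured vitellogenins, 6 fell (median -3.80, camera adjusted p = 1.2e-04, or 0.16 at estimated correlation). The yolk gene vit-5 fell 36.8-fold (log2 -5.20 ± 0.09). Of 36 measured germline and oocyte markers, 36 fell (median -2.01, camera adjusted p = 1.0e-14, or 0.057 at estimated correlation). The gene oma-2 fell 9.67-fold (log2 -3.27 ± 0.06). Of 158 measured cuticle collagens, 118 rose, 24 fell and 16 were not called (median 1.81, camera adjusted p = 2.1e-12, or 0.14 at estimated correlation). The collagen sqt-3 rose 7.21-fold (log2 2.85 ± 0.06). Of 31 measured epidermis and seam markers, 25 rose, 4 fell and 2 were not called (median 2.58, camera adjusted p = 9.3e-08, or 0.07 at estimated correlation). The gene mlt-8 rose 7.66-fold (log2 2.94 ± 0.06). Of 38 measured neuron markers, 31 rose, 2 fell and 5 were not called (median 0.70, camera adjusted p = 1.7e-05, or 0.011 at estimated correlation). Of these, egl-3 rose 1.91-fold (log2 0.94 ± 0.05). Of 14 measured pharynx markers, 13 rose and 1 was not called (median 0.88, camera adjusted p = 2.0e-04, or 0.13 at estimated correlation). The gland gene phat-1 rose 6.75-fold (log2 2.75 ± 0.11). Of 33 measured proteasome subunits, 33 fell (median -0.79, camera adjusted p = 2.3e-10, or 0.025 at estimated correlation). The subunit rpn-9 fell 2.01-fold (log2 -1.01 ± 0.05). Of 221 measured nuclear hormone receptors, 140 rose, 16 fell and 65 were not called (median 0.61, camera adjusted p = 1.9e-05, or 0.0045 at estimated correlation). The receptor nhr-97 rose 1.97-fold (log2 0.98 ± 0.05). In the intracellular pathogen response, 29 rose, 2 fell and 12 were not called (median 0.63, camera adjusted p = 0.0037, or 0.18 at estimated correlation), with skr-3 up 1.57-fold (log2 0.65 ± 0.05). Among metal handling genes, 16 rose, 4 fell and 6 were not called (median 0.85, 0.74 with genes at 0 at their bound, camera adjusted p = 0.0066, or 0.057 at estimated correlation), with hrg-2 up 4.95-fold (log2 2.31 ± 0.07). In fatty acid oxidation, 4 rose, 30 fell and 10 were not called (median -0.67, camera adjusted p = 1.2e-04, or 0.025 at estimated correlation), with acdh-1 down 2.90-fold (log2 -1.54 ± 0.06). Over all genes, edgeR called 6895 higher and 6330 lower. Of the 34 lists 21 were called, and 4 with an estimated correlation. Of the 37 genes picked for this comparison, 36 were called by edgeR, with a largest adjusted p of 0.016, for unc-32. Adjusted over the list alone, member counts (higher, lower) differed, among the lists named here, for nuclear hormone receptors (139, 16) and fatty acid oxidation and catabolism (4, 32).

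Combination worms were also compared with control. Higher in them were 38 of 43 genes of the intracellular pathogen response and 117 of 158 cuticle collagens. Lower were 6 of 6 vitellogenins, 35 of 36 germline and oocyte markers and 36 of 44 genes of fatty acid oxidation. Rises were F10A3.1 (707-fold, log2 9.47 ± 0.22), T22F3.11 (531-fold, log2 9.05 ± 0.18), C17H1.6 (427-fold, log2 8.74 ± 0.24) and T25B6.6 (388-fold, log2 8.60 ± 0.25). The gene spp-21 rose at least 240.3-fold. Control counts of 1 to 3 were found for C17H1.10 (ratio 937, exact 95% interval 320.4 to 4546) and the chemoreceptor gene sri-70 (ratio 724, exact 95% interval 200.3 to 5986). Falls were vit-4 (17726-fold, log2 -14.11 ± 0.14), vit-5 (3903-fold, log2 -11.93 ± 0.10), vit-2 (819-fold, log2 -9.68 ± 0.12) and pud-3 (1392-fold, log2 -10.44 ± 0.16). Combination counts of 1 to 3 were found for pud-4 (ratio 3.62e-04, exact 95% interval 9.17e-06 to 0.00202), ZC376.2 (ratio 6.14e-04, exact 95% interval 7.43e-05 to 0.00222) and the acyl-CoA oxidase F08A8.4 (ratio 9.93e-04, exact 95% interval 1.20e-04 to 0.00359). The target vha-6 fell 27.2-fold (log2 -4.76 ± 0.07), cpr-5 fell 31.1-fold (log2 -4.96 ± 0.07), elt-7 1.78-fold (log2 -0.83 ± 0.14) and vha-7 2.64-fold (log2 -1.3997 ± 0.06). Higher were elt-2 4.53-fold (log2 2.18 ± 0.15), hlh-30 2.58-fold (log2 1.37 ± 0.06), unc-32 1.18-fold (log2 0.23 ± 0.05) and vha-5 1.09-fold (log2 0.13 ± 0.06), the last with a negative value under DESeq2 size factors, where unc-32 was not called.

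Of 33 measured cathepsin-type proteases, 12 rose, 19 fell and 2 were not called (median -0.83, -0.69 with genes at 0 at their bound, camera adjusted p = 0.06, but 0.009 with library size alone). Here cpr-3 (70.1-fold, log2 6.13 ± 0.07) rose and F13D12.6 (17.3-fold, log2 -4.12 ± 0.06) fell. For lysosomal lipid, sugar and nucleic acid hydrolases, 11 rose, 17 fell and 4 were not called (median -0.42, but 0.07 with library size alone, camera adjusted p = 0.069, but 0.037 with library size alone). The lipase lipl-5 fell 24.6-fold (log2 -4.62 ± 0.06). For autophagy genes, 11 rose, 16 fell and 1 was not called (median -0.31, but 0.18 with library size alone, mean 0.10 and test direction lower, camera adjusted p = 0.6), with sqst-1 up 8.41-fold (log2 3.07 ± 0.06). Of 43 measured genes of the intracellular pathogen response, 38 rose and 5 were not called (median 5.24, 5.14 with genes at 0 at their bound, camera adjusted p = 1.5e-08, or 0.045 at estimated correlation). The gene eol-1 rose 329-fold (log2 8.36 ± 0.11). Among antimicrobial effectors, 27 rose, 42 fell and 7 were not called (median -1.097, camera adjusted p = 0.069, but 0.0017 with library size alone). Of these hpo-6 (9.16-fold, log2 3.195 ± 0.06) rose and lys-1 (27.3-fold, log2 -4.77 ± 0.06) fell. For DAF-16 targets, 9 rose, 14 fell and 2 were not called (median -0.38, but 0.11 with library size alone, camera adjusted p = 0.28), with tts-1 up 88.96-fold (log2 6.48 ± 0.08). For metal handling, 10 rose, 13 fell and 3 were not called (median -0.09, but 0.40 with library size alone, camera adjusted p = 0.97), with hrg-2 up 256-fold (log2 8.001 ± 0.14). Of 44 measured genes of fatty acid oxidation and catabolism, 6 rose, 36 fell and 2 were not called (median -1.18, camera adjusted p = 1.1e-06, or 0.0079 at estimated correlation). The dehydrogenase acdh-1 fell 25.7-fold (log2 -4.68 ± 0.07). The P450 cyp-33C8 rose 33.2-fold (log2 5.05 ± 0.07). Of 6 measured vitellogenins, 6 fell (median -9.38, camera adjusted p = 4.3e-05, or 0.18 at estimated correlation). Of 158 measured cuticle collagens, 117 rose, 28 fell and 13 were not called (median 2.34, camera adjusted p = 2.3e-07, or 0.31 at estimated correlation). The collagen dpy-13 rose 13.2-fold (log2 3.73 ± 0.06). Of 36 measured germline and oocyte markers, 35 fell and 1 was not called (median -2.17, camera adjusted p = 5.8e-12, or 0.1 at estimated correlation). The gene oma-2 fell 11.2-fold (log2 -3.48 ± 0.06). Of 33 measured proteasome subunits, 32 fell and 1 was not called (median -0.98, camera adjusted p = 8.5e-10, or 0.028 at estimated correlation). The subunit pas-4 fell 2.62-fold (log2 -1.39 ± 0.05). Of 38 measured neuron markers, 34 rose, 1 fell and 3 were not called (median 1.35, camera adjusted p = 2.1e-06, or 0.0067 at estimated correlation). The protease egl-3 rose 3.60-fold (log2 1.85 ± 0.05). Over all genes, edgeR called 8169 higher and 6915 lower, or 10084 and 5058 with library size alone. Of the 34 lists 18 were called, 16 with the replicate number as a block and 5 with an estimated correlation. Of the 37 genes picked for this comparison, 37 were called by edgeR, with a largest adjusted p of 0.036, for vha-5. Adjusted over the list alone, member counts (higher, lower) differed, among the lists named here, for metal handling (11, 13) and cuticle collagens (118, 28).

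Whether the effect of vha-6 RNAi differs when elt-2 RNAi is fed too was tested as an interaction, the log2 effect of vha-6 RNAi in worms fed elt-2 RNAi minus that in worms without it. A negative value means a smaller rise, a rise turned into a fall, or a larger fall with elt-2 RNAi fed, and list medians are of log2 interactions. For cathepsin-type proteases, the interaction was higher for 6, lower for 20 and not called for 7 (median -1.56, camera adjusted p = 3.2e-05, or 0.12 at estimated correlation). The protease asp-12 was at 6.37 ± 0.273, 852 ± 51.7, 62.995 ± 2.95 and 35.4 ± 1.197 CPM in control, vha-6, elt-2-labelled and combination libraries, an interaction of -7.89 ± 0.09. That of cpr-3 was -4.22 ± 0.09, and cpl-1 (1.06 ± 0.07) lay on the positive side. For cpr-5 it was -0.77 ± 0.10, for hlh-30 -0.83 ± 0.08, for elt-7 -0.65 ± 0.20 and for vha-5 0.26 ± 0.08. The interactions of vha-6 (0.03 ± 0.09), elt-2 (0.01 ± 0.20), vha-7 (0.07 ± 0.08) and unc-32 (0.05 ± 0.07) were not called with TMM scaling, and those of vha-6, vha-7 and unc-32 were called with DESeq2 size factors, whereas that of elt-7 was not.

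Except for asp-12, the lowest interactions among genes picked by the rule were of genes under 1 CPM in control. Values follow in the order control, vha-6, elt-2-labelled and combination CPM. The lectin clec-70 was at 0.170 ± 0.151, 26.6 ± 1.13, 0.151 ± 0.0302 and 0 ± 0, and ugt-18 at 0.170 ± 0.00209, 104.04 ± 4.66, 0.246 ± 0.0717 and 0.230 ± 0.125. The lectin clec-9 was at 0.0753 ± 0.0432, 35.3 ± 3.12, 0.165 ± 0.0254 and 0.119 ± 0.0674, and ech-9 at 0.349 ± 0.168, 169.8 ± 7.16, 0.0979 ± 0.0157 and 0.199 ± 0.103. In contrast, T22F3.11 was at 0.773 ± 0.223, 386 ± 72.0, 368 ± 18.05 and 411 ± 15.1, and spp-21 at 0 ± 0, 0.946 ± 0.232, 16.37 ± 0.218 and 20.4 ± 2.09, both higher in the libraries labelled elt-2 RNAi than in control. Positive interactions were found for vit-3 (6.17 ± 0.11), vit-1 (4.80 ± 0.09), vit-4 (3.82 ± 0.42), Y48E1B.8 (5.19 ± 0.25) and dod-23 (3.56 ± 0.09). The gene pud-3 was at 209 ± 14.2, 0.376 ± 0.259, 2.76 ± 0.284 and 0.147 ± 0.0228, and asm-3 at 46.5 ± 6.97, 1.38 ± 0.314, 0.217 ± 0.0697 and 0.128 ± 0.0159. For vitellogenins, the interaction was higher for 5 and not called for 1 (median 3.197, camera adjusted p = 6.7e-08, or 0.083 at estimated correlation).

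For lysosomal lipid, sugar and nucleic acid hydrolases, the interaction was higher for 2, lower for 20 and not called for 10 (median -0.84, camera adjusted p = 0.0015, or 0.055 at estimated correlation). Examples were gba-1 (-4.12 ± 0.10) and asah-1 (-3.14 ± 0.11). For autophagy genes, the interaction was higher for 1, lower for 15 and not called for 12 (median -0.23, but 0.05 with DESeq2 size factors, camera adjusted p = 0.15), and sqst-1 was at -2.32 ± 0.08. For antimicrobial effectors, the interaction was higher for 8, lower for 52 and not called for 16 (median -1.39, camera adjusted p = 1.8e-05, or 0.055 at estimated correlation), with examples lys-2 (-3.25 ± 0.08) and spp-2 (-4.204 ± 0.11). Among DAF-16 targets, the interaction was higher for 3, lower for 13 and not called for 9 (median -0.67, camera adjusted p = 0.16, but 0.043 with DESeq2 size factors), and tts-1 was at -5.57 ± 0.09. For metal handling, the interaction was higher for 7, lower for 11 and not called for 8 (median -0.48, camera adjusted p = 0.56), and for oxidative stress and glutathione genes, the interaction was higher for 9, lower for 18 and not called for 34 (median -0.06, but 0.22 with DESeq2 size factors, mean -0.12 and test direction higher, camera adjusted p = 0.35), with examples hrg-3 (-5.60 ± 0.13) and gst-10 (3.48 ± 0.18). For fatty acid oxidation, the interaction was higher for 12, lower for 24 and not called for 8 (median -0.31, camera adjusted p = 0.79), and acdh-1 was at 2.12 ± 0.09. For nuclear hormone receptors, the interaction was higher for 6, lower for 107 and not called for 108 (median -0.54, camera adjusted p = 5.3e-04, or 0.019 at estimated correlation), and nhr-31 was at -1.43 ± 0.08. For cuticle collagens, the interaction was higher for 31, lower for 89 and not called for 38 (median -0.85, camera adjusted p = 0.0059, or 0.51 at estimated correlation), and dpy-13 was at -1.49 ± 0.08. For molting genes, the interaction was higher for 1, lower for 20 and not called for 4 (median -0.75, camera adjusted p = 1.7e-04, or 0.16 at estimated correlation), and mlt-9 was at -1.51 ± 0.10. For germline and oocyte markers, the interaction was higher for 25, lower for 1 and not called for 10 (median 0.60, camera adjusted p = 5.5e-15, or 0.057 at estimated correlation), and puf-5 was at 1.24 ± 0.08. For ribosomal proteins, the interaction was higher for 76 and not called for 5 (median 0.36, camera adjusted p = 4.6e-24, or 0.18 at estimated correlation), with rps-28 at 0.74 ± 0.09. For proteasome subunits, the interaction was higher for 28 and not called for 5 (median 0.27, camera adjusted p = 5.4e-12, or 0.032 at estimated correlation), with pas-4 at 0.48 ± 0.08.

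Over all genes the interaction was higher for 2182 and lower for 5621 by edgeR, or 4994 and 3583 with DESeq2 size factors, so the balance of directions depended on scaling. Of the 34 lists 20 were called, and 2 with an estimated correlation. Of the 39 genes picked for this comparison, 35 were called by edgeR, with a largest adjusted p of 0.0068, for vha-5. Adjusted over the list alone, member counts (higher, lower) differed, among the lists named here, for cathepsin-type proteases (6, 21), antimicrobial and immune effectors (10, 52), insulin pathway (DAF-16) targets (5, 13), metal handling (8, 11), fatty acid oxidation and catabolism (13, 25), nuclear hormone receptors (6, 114), cuticle collagens (31, 91), cytosolic ribosomal proteins (79, 0) and proteasome subunits (30, 0). Of the 8756 genes higher with vha-6 RNAi, 4981 had a lower interaction, and 3400 with DESeq2 size factors. Of the 6186 lower with it, 1913 had a higher and 346 a lower interaction. Among those 4981 genes, 3503 (70.3%) were still higher in the combination than in the libraries labelled elt-2 RNAi. In those libraries 4139 (83.1%) were already higher than in control, and 1507 (30.3%) were lower in the combination than with vha-6 RNAi alone. Of the 20 cathepsin-type proteases among the 4981 genes, 18 were lower in the combination than with vha-6 RNAi alone. In the combination 15 were still higher than in the libraries labelled elt-2 RNAi. In those libraries 8 of the 20 were higher and 12 lower than in control. The effects of vha-6 RNAi without and with elt-2 RNAi, which share no libraries, had r = 0.839 across 17479 genes, which are not independent replicates, with a slope of 0.593. There were 6315 genes higher in both (3454 for independent lists) and 5568 lower in both (2240.3).

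**Figure D3:**
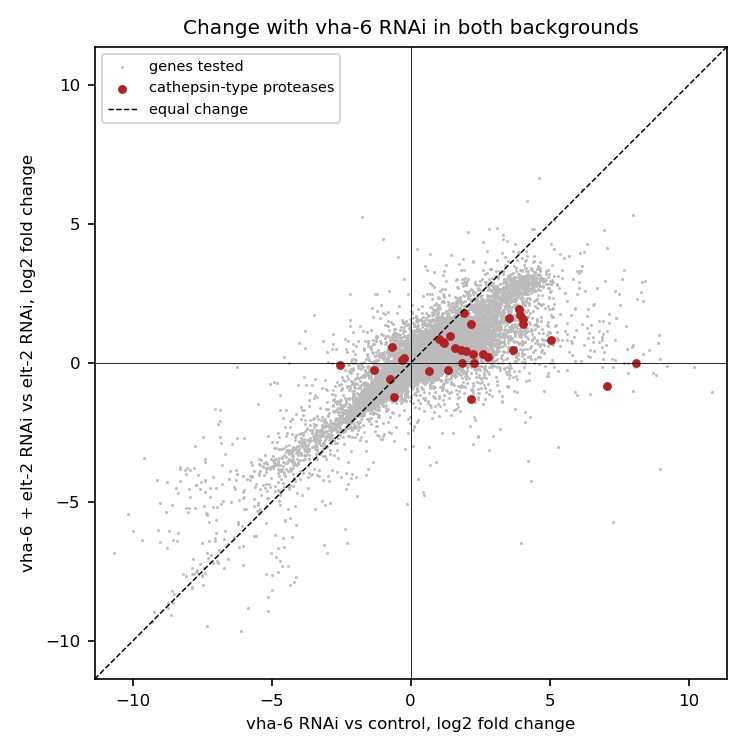
Log2 fold change of each tested gene with vha-6 RNAi against control (x axis) and in the combination against the libraries labelled elt-2 RNAi (y axis), with cathepsin-type proteases in red and a dashed line of equal change. Most proteases lie to the right of 0 and below the line, and for the 33 measured the median interaction was -1.56.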

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

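The other splits of the libraries and the test of selection were planned before the results were seen; the tests of weaker vha-6 RNAi, of scaling and of the spread in relabeled groups were chosen after. The effect of vha-6 RNAi differed between worms fed and not fed elt-2 RNAi, by a test of the difference itself, for 2182 genes with a higher and 5621 with a lower interaction. For 20 of 34 gene lists the difference was also called, but for only 2 of these 20 with an estimated correlation. Among named genes, log2 interactions were -0.65 for elt-7 (not called with DESeq2 size factors, -0.38), -0.83 for hlh-30, -0.77 for cpr-5, 0.26 for vha-5 and -7.89 for asp-12. They were 6.17 for vit-3, 4.80 for vit-1, 3.82 for vit-4, 5.19 for Y48E1B.8 and 3.56 for dod-23. Fitted values of 4.92 for pud-3, 4.31 for asm-3, -12.99 for clec-70, -9.36 for ugt-18, -9.26 for clec-9, -8.04 for spp-21 and -7.90 for ech-9 depend on the prior count, since a group is at or near 0. For T22F3.11 (-8.80) the transcript was at a like level in the 3 RNAi groups, so its negative value reflects a high level in the libraries labelled elt-2 RNAi.

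Of 100 relabelings of the 12 libraries, 1, the real one, gave as many interaction genes (7803, highest other 1529). For lists, 31 of 100 gave at least 20 (highest other 27), and for genes higher with vha-6 RNAi that had a lower interaction, 1 of 100 gave as many (4981, highest other 183). Relabeling also mixes the effects of each RNAi into the groups: the biological coefficient of variation was 6.18% in the real groups and at least 42.6% in the 99 others, 95 of which called 0 genes. These splits therefore do not test the interaction with those effects kept, and do not decide whether chance can be excluded. With those effects kept, 20 simulations with additive effects called at most 1 interaction gene each, under TMM scaling and under DESeq2 size factors. Between groups of 3 and 3 there are only 10 splits, too few for a share under 0.05. In the order of comparisons of the report, the real splits called 14942, 9807, 6308, 13225 and 15084 genes, with a highest other of 0 in each, and 22, 27, 31, 21 and 18 lists, with highest others of 19, 24, 25, 20 and 16.

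Of 8756 genes higher with vha-6 RNAi, 4981 (56.9%) had a lower interaction, against 3400 of 7734 with DESeq2 size factors (over all genes 4994 higher, 3583 lower). Of the 6186 lower with it, 1913 (30.9%) had a higher interaction. For cathepsin-type proteases the median interaction was -1.56 (camera adjusted p = 3.2e-05, but 0.12 with an estimated correlation). Weaker vha-6 RNAi in the mixture is argued against only as a smaller fold fall. The vha-6 interaction had an upper 95% limit of 0.239 (value 0.31 with DESeq2 size factors) against a fall of 2.23. A smaller CPM loss (from 56.5 in elt-2-labelled, 334 in control) stays open. Scaling moved the count of 4981 but is argued against for the proteases (median nearest to 0 over 3 scalings -1.28). Selection of genes high by chance was not decided. The 20 simulations with additive effects gave at most 1 such gene, but with no interaction simulated, few calls follow by construction. Their noise was the spread between these libraries, which may be technical. An effect of lowered elt-2 was not tested, since elt-2 counts were not lower in the libraries labelled elt-2 RNAi. In those libraries 83.1% of the 4981 genes were already higher than in control, against 37.5% of all tested genes.

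Outside the genes, multimapped reads fell from 5.26% in control to 3.56% with vha-6 RNAi, 2.66% in the libraries labelled elt-2 RNAi and 3.41% in the combination. Reads with no annotated feature rose from 0.710% to 0.951%, 0.934% and 1.19% in that order. Ambiguous reads were at 1.401% and 1.42% in the groups fed elt-2 RNAi against 1.31% in control.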

How the results depend on the processing

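The settings that combine a 2-fold minimum with another scaling, and gene lists with DESeq2 size factors, were chosen after seeing the data; the other alternatives were fixed in advance. Counts of genes higher and lower follow in the order vha-6 RNAi against control, libraries labelled elt-2 RNAi against control, combination against vha-6 RNAi, combination against libraries labelled elt-2 RNAi, combination against control, and interaction. The main counts were 8756 and 6186, 6553 and 3254, 2930 and 3378, 6895 and 6330, 8169 and 6915, and 2182 and 5621. With a minimum of 2-fold they were 6209 and 3169, 2646 and 1018, 654 and 1250, 2918 and 2647, 6039 and 3706, and 456 and 2407. With DESeq2 size factors they were 7734 and 6878, 4731 and 5779, 4061 and 2827, 7125 and 6198, 7525 and 7446, and 4994 and 3583, with the DESeq2 test 7684 and 6854, 4715 and 5752, 4016 and 2789, 7011 and 6179, 7488 and 7429, and 4979 and 3549, and with library size alone 9800 and 5312, 10711 and 1722, 7500 and 2036, 8333 and 5434, 10084 and 5058, and 1765 and 6105. With the 2-fold minimum and DESeq2 size factors they were 5104 and 4171, 1732 and 1254, 720 and 1180, 3063 and 2512, 5284 and 4516, and 743 and 1483, and with the 2-fold minimum and library size alone 7452 and 2199, 4317 and 829, 956 and 1072, 4099 and 1849, 7897 and 1884, and 418 and 2679. Without the low-count filter, on only the groups compared, after thinning to the smallest library and with the replicate number as a block, each of these 12 counts stayed within 1.5 times the main count. Genes higher with vha-6 RNAi that had a lower interaction numbered 4981, or 2263 at 2-fold, 1389 at 2-fold with DESeq2 size factors and 2575 at 2-fold with library size alone. A higher fold minimum removes calls by construction, and the scalings shift all genes together by the medians given below, while for other moves the cause was not tested.

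Median shifts of all genes with DESeq2 size factors were -0.25, -0.21, 0.07, 0.03, -0.18 and 0.28 on the log2 scale in that order, and with library size alone 0.26, 0.28, 0.23, 0.20, 0.49 and -0.06. Leaving out each library in turn gave 8548 to 8630 higher and 6123 to 6163 lower, 6140 to 6219 and 3003 to 3085, 2433 to 2836 and 3008 to 3310, 6452 to 6552 and 6211 to 6235, 7989 to 8034 and 6843 to 6857, and for the interaction 1980 to 2214 and 5300 to 5601. No count moved by over 1.5 times. Gene lists called, from 22, 27, 31, 21, 18 and 20 of 34, fell to 3, 14, 15, 4, 5 and 2 with an estimated correlation. With the replicate block they were 22, 27, 31, 21, 16 and 20, with the nutrient sensing and oxidative stress lists lost in the combination against control. With library size alone they were 21, 25, 29, 20, 20 and 19, with 2, 3, 4, 3, 2 and 1 lists lost and 1, 1, 2, 2, 4 and 0 gained. Gained in the combination against control were cathepsin-type proteases, lysosomal hydrolases, antimicrobial effectors and sperm markers, and with vha-6 RNAi V-ATPase subunits. Of the lists lost, germline markers in the libraries labelled elt-2 RNAi and ribosomal proteins in the combination against vha-6 RNAi also changed test direction. With DESeq2 size factors they were 22, 25, 31, 21, 17 and 21, with 0, 3, 1, 0, 1 and 2 lost and 0, 1, 1, 0, 0 and 3 gained. The labels do not say that a replicate number marks a shared batch, and 7 of 18 same-number pairs had a correlation of deviations over 0.1, so pairing was not established. In 1 of the 12 libraries the best match in every other group had its own number.

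Of 250 results for named genes, 232 kept their direction and side of the threshold under the alternatives run on them. Of 3482 values, 3425 stayed the same, 19 passed the threshold, 12 lost it and 26 changed sign. The changes of sign were as follows. For vha-6 RNAi against control, vha-5 was -0.19 with DESeq2 size factors, -0.19 with the DESeq2 test and -0.098 on the groups compared, and unc-32 -0.17, -0.17 and -0.074. For the libraries labelled elt-2 RNAi, unc-32 was -0.10, -0.10 and -0.0089 under the same settings, and with library size alone vha-5 was 0.095 and vha-7 0.25. Leaving out libraries gave -0.076 to 0.0013 for vha-7 there. With library size alone hlh-30 was 0.15 in the combination against vha-6 RNAi. Against control, vha-5 in the combination was -0.052 with DESeq2 size factors and -0.052 with the DESeq2 test. For the interaction with library size alone, vha-6 was -0.025, elt-2 -0.045 and unc-32 -0.0039, and leaving out libraries gave -0.073 to 0.097 for vha-6 and -0.12 to 0.16 for elt-2. Among these values, adjusted p was under 0.05 with the opposite sign for vha-5 and unc-32 with vha-6 RNAi (DESeq2 size factors and DESeq2 test). The same held for vha-7 (library size alone) and unc-32 (DESeq2 test) in the libraries labelled elt-2 RNAi, and for hlh-30.

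Calls were lost as follows. In the libraries labelled elt-2 RNAi, vha-5 was -0.13 without their replicate 3. In the combination against vha-6 RNAi, unc-32 was 0.14 without combination replicate 1. Against the libraries labelled elt-2 RNAi, unc-32 was 0.10 without their replicate 3 and 0.10 without combination replicate 1. Against control, vha-5 was 0.12 and 0.082 without control replicates 1 and 2, and 0.10 and 0.13 without combination replicates 1 and 3, each left out singly. With DESeq2 size factors and with the DESeq2 test, unc-32 was 0.056 there and the interaction of elt-7 was -0.38.

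Calls were gained as follows. With library size alone, vha-5 was 0.31 and unc-32 0.34 for vha-6 RNAi against control, unc-32 0.39 in the libraries labelled elt-2 RNAi, and vha-5 0.30 and vha-7 0.26 in the combination against vha-6 RNAi. Against the libraries labelled elt-2 RNAi, elt-7 was 0.50 with that setting and 0.33 with DESeq2 size factors or the DESeq2 test. In those libraries vha-7 was -0.25 with either of these and -0.15 on the groups compared, and unc-32 was 0.13 without their replicate 3. With DESeq2 size factors vha-5 was 0.14 in the combination against vha-6 RNAi. Interactions with DESeq2 size factors and with the DESeq2 test were 0.31 for vha-6, 0.34 for vha-7 and 0.33 for unc-32. The cause of these moves was not tested. No pseudocount alternative applied, since counts were tested. With 3 libraries a group, the smallest permutation p for a single gene between a pair of groups is 0.1. In simulated data 46% of the smallest changes were recovered for vha-6 RNAi against control.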

Other observations

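The 6 gene lists in the first paragraph and the tests in the other paragraphs were chosen after the values were seen. With vha-6 RNAi against control, of 22 DNA replication genes 0 rose and 22 fell (median -1.57, camera adjusted p = 3.7e-10, or 0.002 at estimated correlation). Of 50 hedgehog-related genes, which encode secreted proteins of the epidermis and other tissues, 41 rose and 4 fell (median 2.94, camera adjusted p = 3.7e-06, or 0.0086 at estimated correlation). Of 102 neuropeptide genes 87 rose and 4 fell (median 1.62, camera adjusted p = 1.5e-08, or 0.042 at estimated correlation), and of 224 chemoreceptor genes 131 rose and 16 fell (median 1.62, camera adjusted p = 0.0027, or 0.0086 at estimated correlation). Of 314 F-box genes 129 rose and 139 fell (median -0.08, but 0.18 with library size alone, camera adjusted p = 0.12), and of 94 MATH and BTB domain genes 42 rose and 32 fell (median 0.18, but -0.06 with DESeq2 size factors, camera adjusted p = 0.51). In the combination against the libraries labelled elt-2 RNAi, DNA replication genes were again lower: 0 rose and 21 fell (median -1.62, camera adjusted p = 1.5e-10, or 0.0017 at estimated correlation).

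The elt-2 transcript was 1.60 times the control level in the libraries labelled elt-2 RNAi and 1.62 times the vha-6 RNAi level in the combination. A swap of the control and elt-2 labels is argued against: of 70 measured members of 3 intestinal lists, 45 were called lower and 18 higher in the libraries labelled elt-2 RNAi, 71.4% lower (exact 95% interval 58.7 to 82.1). Reads of the fed double-stranded elt-2 RNA are a candidate explanation and stay open. The added elt-2 counts were 6.77 ± 1.99 CPM without and 19.4 ± 5.53 with vha-6 RNAi (difference of means ± SE), 2.15 standard errors apart, between the limits set for and against. The spread of elt-2 between the 3 libraries, 19.02% and 18.7% of the mean, exceeded that of 99.5% and 99.9% of genes of like level. A regulated rise of the elt-2 gene itself was not tested.

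With vha-6 RNAi 36 of 36 germline markers fell, while 24 of 25 molting genes and most of 158 cuticle collagens (28 fell, 11 not called) rose, none of the 3 lists called with an estimated correlation (adjusted p = 0.096, 0.13 and 0.22). A smaller germline share of the RNA would raise somatic markers alike and stays open as a partial cause. The median of 13 epidermis markers outside the collagen and molting lists (0.63, quartiles -0.30 and 3.93) exceeded that of 28 body muscle markers (0.23) by 0.40 (permutation p = 0.044, two-sided, 100000 resamples), under the limit of 1 set against it. A first version took all 31 epidermis markers (median 3.45), 18 of them in the lists to be explained, and argued against it. Medians were 1.19 for neuron and 1.12 for pharynx markers. An earlier stage at collection was not decided. The 7 collagens of the last larval stage had a median log2 change of 4.27 (4.02 to 4.64). The 7 adult genes, among them yolk genes and the germline marker rme-2, had -3.98 (upper quartile 0.13). Collagens and rme-2 are in the lists to be explained. The split was made after the values were seen. A first adult set left out col-7 (1.27) and col-62 (1.299), which rose against a stage shift.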
